A study of Arabidopsis thaliana with 51 samples.

How the data were processed

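Genomic DNA from pooled flowers of Arabidopsis thaliana was bisulfite treated and sequenced, per the labels' protocols, which state that each replicate pooled flowers of 5 to 10 lines sharing a phenotype and that BGI made and sequenced the libraries. The submitters' processing notes name Bismark, HISAT2, FastQC 0.11.9 and the genome build TAIR10, without roles or order. The coverage minimum, the conversion rate and the treatment of cytosines without reads are not given in the sources used here.

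The deposited table holds, per the file headers, a context and a coordinate for 5709 cytosine entries and a column for each of 51 libraries. Its deposited values are methylation levels in whole percent from -100 to 100, in which a minus sign marks a strand. The sign was removed before any level was computed. The table gives neither methylated read counts nor coverage, so the depth behind every level is unknown, no confidence interval or detection limit was computed for a level, and a value of 0 can stand for an unmethylated or for an uncovered cytosine. The entry rc, whose meaning the table does not state, and empty entries were treated as missing. No pair of libraries held identical values.

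The columns fell into 5 blocks whose rows were not all in step with the coordinates. In column block 1 (11 libraries) signs were opposite within CpG and CHG dyads, plus at the lower coordinate and minus at the higher. Among 506 rows 1 conflicted with this, and this block served as the reference. In column blocks 2 to 5 the sign matched the strand in 65.6%, 59.4%, 54.5% and 63.0% of the rows compared. A hidden Markov model of the signs, with displacements up to 40 rows, a sign error rate of 0.003, a rate of displacement change of 0.004 and a least posterior of 0.9, brought the rows of each block into register. The sign then matched in 100.0%, 99.953%, 100.0% and 99.957% of the rows compared, and 94.8% to 95.7% of rows were kept. The magnitudes, which the model did not use, served as a check. Pearson's r across cytosines between replicates A and B of Col AGe rMf moved from 0.744 to 0.930, and between replicates A and C of Col Wt from 0.342 to 0.743. On simulated displacements, 99.65% to 99.67% of the kept rows were right, against 38.5% without the model. Leaving out 68 rows that share a coordinate with another left 5641, of which the 5165 that the realignment placed in all 5 column blocks were analysed. In set A, replicate A lies in column block 1 and replicates B and C in column block 2, so differences are also given within each column block.

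Levels were averaged over cytosines, each with equal weight. Because the table names no regions, 3 domains were defined after the data were seen, from the Col AGp//AGe sMf library, which entered no test. The domains are runs of 100-bp windows with a mean level of at least 10%, at least 5 windows long, with gaps of up to 5 lower windows bridged. In that library 3, 17 and 24 windows reached 10% in the domains named CpG-only, AGp and AGe below, of 700, 2200 and 2800 bp. The 30 level differences over the whole table within a single context were planned. The other 170, over the domains, outside them or over the whole table with all contexts pooled, were not planned. Each was tested with a two-sided exact permutation test over libraries with Benjamini-Hochberg adjustment. The smallest p-value this test can give is 0.1 for 3 libraries against 3 or 2, and 0.333 for 2 against 2, so no level difference could pass 0.05.

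Single cytosines were tested with limma 3.58.1 in R 4.3.3, with a trended empirical Bayes variance, on log2((p + 0.01)/(1 - p + 0.01)), where p is the level as a fraction. A single fit covered the 23 libraries of the 9 replicated groups of set A and the 2291 cytosines above 0 in at least 2 of them. This filter was chosen after the data were seen. Cytosines with a Benjamini-Hochberg adjusted p-value under 0.05 were called. The fit was tested on simulated data built on M317 AGe rMf against M317 Wt. It recovered 48% of 50 cytosines shifted by 2 log2 units, 96% of those shifted by 4 and 100% of those shifted by 6 or 8, and called 5 of 2091 unshifted cytosines (2.82% of its calls). Residuals were shuffled within each cytosine over all 23 libraries, so the simulated groups shared a common spread. The share of false calls need not hold where real groups are listed at 0 and have no spread. A log2 odds difference against a group listed at 0 depends on the offset of 0.01 and is no bound.

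Groups were taken from the labels' genotype, construct and flower phenotype. The 10 comparisons, the test, the limma design and the rule for named sites were fixed before the data were examined. Named sites are the 5 called cytosines per context with the largest gain and the largest loss whose libraries did not overlap between the groups, and the 5 windows of 100 bp per context with the largest difference. Gene lists fixed with them were not applied, since the rows are cytosines of a single region. The 26 groups with 1 library were described without a test.

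Other settings fixed before the data were examined were no filter, an offset of 0.05, the compared groups alone, a replicate block, the median in place of the mean, and leaving out each library. Settings chosen after the data were seen were a stricter filter (above 0 in at least 5 libraries, in place of a minimum of reads), the rows as deposited, the column block as a covariate, and the comparisons of Wt plants without a segment listed at 0. Explanations were tested with bootstrap intervals (2000 draws, 95%) and counts of other splits of the libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. No TAIR10 annotation was used. From a TAIR10.1 gene table, names and neighbours alone were taken, and no position was transferred between builds.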

Results

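Cytosine methylation was measured by bisulfite sequencing of flower DNA over 17298 bp, from 10374202 to 10391499 in TAIR10, listing 604 CpG, 727 CHG and 4378 CHH entries (H is A, C or T), of which 68 share a coordinate with another and were left out. The table does not name the chromosome. The construct labels AGe and AGp were not spelled out, and the region was taken as that of AG (AT4G18960), a floral organ identity gene of the MADS-box family. In the TAIR10.1 gene table AG lies on chromosome 4 with AT4G18950, AT4G18970 and the long noncoding RNA AT4G06860 as neighbours. Whether a domain lies in an exon, an intron or between genes was not determined. Set A comprised 28 libraries, set B 13 and set C 10. The labels name Col, M317 and M318 plants, the alleles Met1-1, ddm1-1, suvh1-2, hdp1-1 and hdp2-1, the constructs AGe, AGp, AGp//AGe, UF2//AGe, UF4//AGe, ARE//AGe and Ctr//AGe, and the flower phenotypes Wt, sMf, rMf and Sterile. The series title spells ARE out as an anti-RdDM element, RdDM being RNA-directed DNA methylation. The other terms were not explained. Sequencing depth was unknown for every library, and reads from a construct and from the endogenous locus were not told apart.

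Levels were described over 3 domains. The CpG-only domain (10377002 to 10377701) was methylated in CpG in plants with and without constructs, at 54.0% ± 9.64 (SD, n = 2) in Col Wt and 57.3% ± 1.55 (n = 2) in Col AGe rMf. The AGp domain spanned 10380602 to 10382801 and the AGe domain 10384302 to 10387101. CpG sites outside the domains were methylated too, at 5.34% ± 1.32 on average in Col Wt and at 64.6% ± 10.7 in its window from 10390302 to 10390401. Level differences are given with their spread, since the exact permutation test could not reach 0.05 for any group size here, and limma calls refer to single cytosines.

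**Figure D1:**
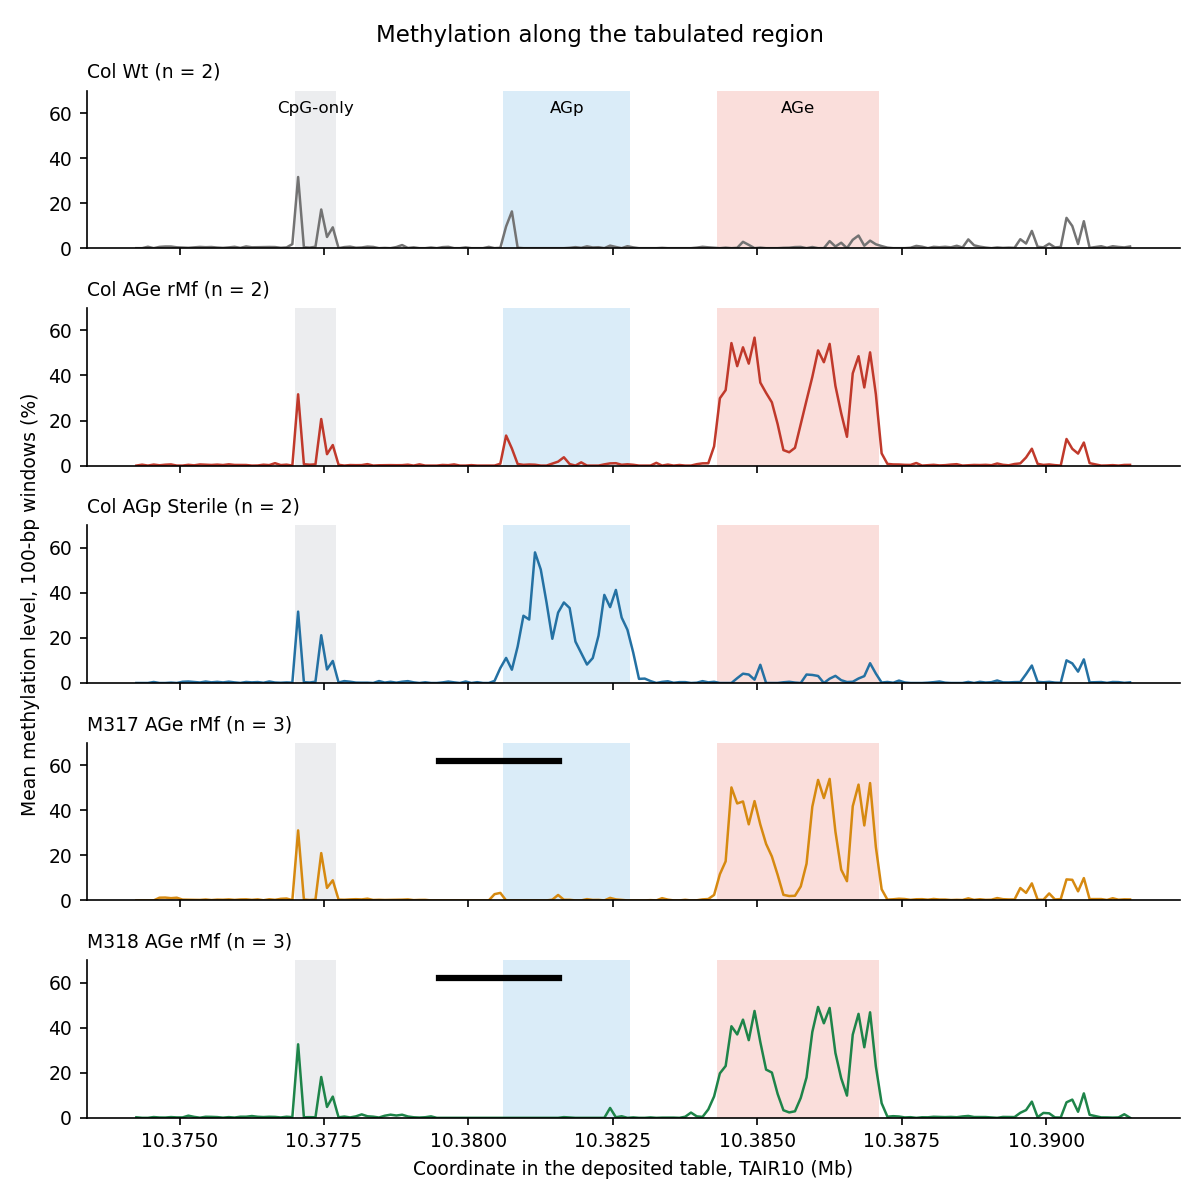
Mean methylation level (%, all contexts) in 100-bp windows along the tabulated region (TAIR10 coordinate, Mb) for 5 groups of set A, with the 3 domains shaded. The AGe domain is methylated in the AGe groups and the AGp domain in Col AGp Sterile. The black bars mark the segment from 10379482 to 10381575 that is listed at 0 in the M317 and M318 libraries of column block 2.

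The first comparison asked how Col plants with AGe and rMf flowers differed from Col Wt. The AGe domain had a mean level of 34.7% ± 2.31 (SD, n = 2) in AGe rMf and 1.08% ± 0.595 (n = 2) in Wt. CHG sites were highest, at 54.6% ± 2.61, followed by CpG at 33.2% ± 2.67 and CHH at 32.8% ± 2.25, whereas in Wt these were 2.52%, 2.08% and 0.850%. The AGp domain was at 1.71% ± 0.990 in AGe rMf and 1.42% ± 0.185 in Wt. The window from 10386902 to 10387001 had a CpG level of 83.5% ± 2.12 against 9.62% ± 0.530, and the window from 10384502 to 10384601 a CHG level of 80.2% ± 7.42 against 0. limma called 658 cytosines higher and 13 lower in AGe rMf, and 636 of the higher ones lay in the AGe domain (41 of 52 CpG, 54 of 65 CHG and 541 of 628 CHH tested). The CpG at 10386326 was at 86.0% ± 2.83 against 0 (limma adjusted p = 3.62e-05) and the CHH site at 10386051 at 76.0% ± 8.49 against 0 (limma adjusted p = 0.00752). Of the 13 lower cytosines, 9 lay in the AGp domain, which also held 5 higher ones. The AGp domain difference was 1.11 percentage points within column block 1 and -0.547 within column block 2. Part of this domain lies in the segment from 10379482 to 10381575, listed at 0 in the M317 and M318 libraries of column block 2. Calls there may be too strong, for the reason given below for AGp Sterile. The AGe domain difference was 34.9 percentage points within column block 1 and 32.4 within column block 2, and the exact permutation p of the pooled difference was 0.333, the smallest possible (adjusted 0.944).

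M317 plants with AGe were compared with M317 Wt. The AGe domain was at 35.0% ± 1.74 (SD, n = 2) in sMf and 29.3% ± 2.26 (n = 3) in rMf, against 1.80% ± 1.90 (n = 3) in Wt, where replicate A was at 3.99% and replicates B and C at 0.722% and 0.690%. CHG sites reached 57.5% ± 3.39 in sMf and 48.6% ± 3.66 in rMf. The AGp domain stayed low, at 0.273% ± 0.340 in sMf, 0.262% ± 0.152 in rMf and 0.221% ± 0.135 in Wt, but part of it lies in a segment listed at 0 in these plants. limma called 643 cytosines higher and 11 lower in sMf, and 558 higher and 12 lower in rMf. Of the higher ones 612 and 539 lay in the AGe domain, with 60 and 53 of 65 CHG, 513 and 463 of 628 CHH, and 39 and 23 of 52 CpG. The CHG at 10386300 was at 90.0% ± 1.41 in sMf (limma adjusted p = 0.000192) and 86.7% ± 2.52 in rMf (limma adjusted p = 0.000105), against 0 in Wt. Within column blocks 1 and 2 the AGe domain difference was 29.8 and 35.6 percentage points for sMf and 22.8 and 29.8 for rMf. Both pooled differences had an exact permutation p of 0.1, the smallest possible (adjusted 0.567).

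M318 plants with AGe were compared with M318 Wt. The AGe domain was at 28.2% ± 2.18 (SD, n = 3) in rMf against 0.719% ± 0.402 (n = 3) in Wt. The sMf libraries differed among themselves, with 31.3% and 26.2% in replicates B and C and 1.54% in replicate A, close to the 0.401% to 1.17% of the Wt libraries. limma called 604 cytosines higher and 14 lower in rMf, of which 576 higher ones lay in the AGe domain (28 of 52 CpG, 52 of 65 CHG and 496 of 628 CHH). In sMf it called 320 higher and 9 lower, with 310 of the higher ones in the AGe domain. The CHG at 10386300 was at 86.0% ± 2.65 in rMf and 0 in Wt (limma adjusted p = 0.000132). The CHH site at 10385937 was at 46.0% ± 18.2 in sMf and 0 in Wt (limma adjusted p = 6.1e-07). The rule of no overlap between groups names only sites with sMf replicate A above 0, so this site need not be typical of the domain. The rMf difference over the AGe domain was 27.5 percentage points in each column block (exact permutation p of the pooled difference 0.1, the smallest possible), whereas the sMf difference was 0.374 in column block 1, which holds replicate A alone, and 28.3 in column block 2. The sMf count was 701 without sMf replicate A, 44 without sMf replicate B or C, 59, 52 and 50 without Wt replicate A, B or C, 49 with no filter, 549 with the stricter filter, 204 with an offset of 0.05, 172 with rows as deposited and 6 with the compared groups alone.

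**Figure D2:**
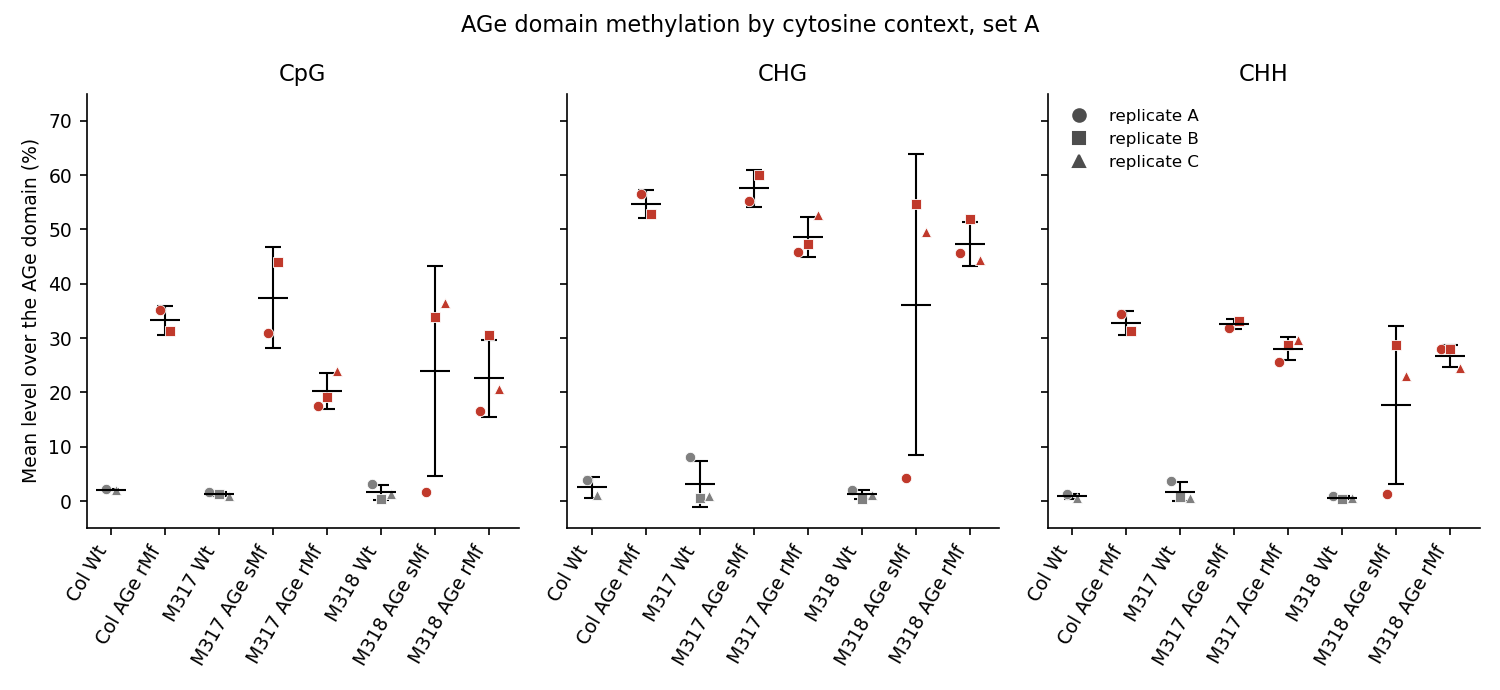
Mean methylation level (%) over the AGe domain in CpG, CHG and CHH context for each library of 8 groups of set A (points, shaped by replicate letter), with the group mean (long bar) and SD (whiskers), n = 2 or 3. Libraries of the AGe sMf and AGe rMf groups lie well above the Wt libraries in every context except M318 AGe sMf replicate A, at 4.32% in CHG.

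The flower phenotypes sMf and rMf were compared within M317 and within M318. In M317 the AGe domain was 5.78 percentage points higher in sMf, without overlap between libraries, and the largest gap was in CpG, at 37.4% ± 9.27 (SD, n = 2) against 20.2% ± 3.29 (n = 3). The CpG level of the window from 10385802 to 10385901 was 62.2% ± 22.3 in sMf and 18.3% ± 14.7 in rMf. This difference over the AGe domain had an exact permutation p of 0.1, the smallest possible (adjusted 0.567), and was 6.99 within column block 1 and 5.79 within column block 2. In M318 the level was 19.7% ± 15.9 (n = 3) in sMf and 28.2% ± 2.18 (n = 3) in rMf, and the difference was -8.54 percentage points with replicate A of sMf and 0.533 without it. It was -27.1 within column block 1 and 0.756 within column block 2.

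limma called no cytosine of the AGe domain between sMf and rMf. In M317 it called 5 cytosines elsewhere (10390390 and 10390393 in CHG, 10377514, 10387232 and 10390468 in CHH), at means of 7.5% to 18% in sMf and 0 in rMf, with 118 at an unadjusted p under 0.05. In M318 it called 1, at 10388310 in CHG, at 12.3% ± 7.09 against 0, with 110 at an unadjusted p under 0.05. Both counts were 0 with the compared groups alone (101 and 8 at an unadjusted p under 0.05) and with the stricter filter (32 and 63). The M317 count was 24 and 50 without sMf replicate A or B and 15, 8 and 8 without rMf replicate A, B or C, and the M318 count 7, 16 and 2 without sMf replicate A, B or C and 10, 3 and 3 without rMf replicate A, B or C.

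M317 Wt and M318 Wt were compared with Col Wt to describe the backgrounds without AGe. The largest listed differences lay at the upstream end of the AGp domain. The 4 CpG of the window from 10380702 to 10380801 were listed at 0 in all M317 Wt and M318 Wt libraries and stood at 61.1% ± 13.6 (SD, n = 2) in Col Wt, and the window from 10380602 to 10380701 was at 0 against 58.0% ± 11.3. Over the AGp domain the CpG level was 1.1% ± 1.90 (n = 3) in M317 Wt, 0.631% ± 0.561 (n = 3) in M318 Wt and 13.3% ± 2.12 in Col Wt. limma called 15 cytosines as listed lower in M317 Wt and 15 lower in M318 Wt, of which 5 CpG, 1 CHG and 7 CHH in each comparison lay in the AGp domain, and 1 higher in M317 Wt. The CpG at 10380748 was at 77.0% ± 8.49 in Col Wt and 0 in both (limma adjusted p = 3.3e-10). All 11 M317 and M318 libraries of column block 2 were listed at 0 at 551 consecutive cytosines from 10379482 to 10381575, while Col Wt replicate C and Col AGe rMf replicate B of that block had 30 and 20 cytosines above 0 there. This segment held both windows named above and 13 of the calls of each comparison. In column block 2 only 2 CHH entries of libraries not used to define it lay above 0, against at least 171 expected of covered cytosines, so these calls are no measure of lower methylation, and without the segment the counts were 1 and 0. Both comparisons share the Col Wt libraries, and the counts were 48 and 51 without Col Wt replicate A and 46 and 45 without Col Wt replicate C. The AGp domain difference was -0.915 and -1.41 percentage points within column blocks 1 and 2 for M317 Wt, and -1.18 and -1.39 for M318 Wt. The segment covers part of the AGp domain, with both windows named above. These differences and the CpG levels of that domain are therefore no measure of lower methylation either.

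Col AGp Sterile was compared with Col Wt. The AGp domain was at 27.5% ± 9.24 (SD, n = 2) against 1.42% ± 0.185 (n = 2), with 39.6% ± 14.4 in CHG, 27.8% ± 11.7 in CpG and 26.1% ± 8.52 in CHH. The AGe domain was at 2.11% ± 0.793 against 1.08% ± 0.595. The window from 10381102 to 10381201 had a CHH level of 57.2% ± 13.7 against 0 in Wt. limma called 490 cytosines higher and 15 lower, and 473 of the higher ones lay in the AGp domain (17 of 26 CpG, 45 of 50 CHG and 411 of 445 CHH). The CHG at 10381220 was at 84.5% ± 9.19 (limma adjusted p = 1.2e-13) and the CHH site at 10381196 at 77.5% ± 13.4 (limma adjusted p = 7.2e-13), both against 0 in Wt. The CpG at 10380748 was lower, at 15.5% ± 6.36 against 77.0% ± 8.49 (limma adjusted p = 3.3e-07). These named cytosines lie in the segment from 10379482 to 10381575, listed at 0 in the 11 M317 and M318 libraries of column block 2. limma shares a common variance over the 9 groups of the fit. Those zeros may be missing reads and can lower that variance, so p-values and calls in this segment may be too strong. The AGp domain difference was 19.7 percentage points within column block 1 and 32.5 within column block 2 (pooled exact permutation p = 0.333, the smallest possible). The count was 150 and 141 without AGp Sterile replicate 1 or 2, and 14 with the stricter filter, which leaves few cytosines that are above 0 in these libraries alone.

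Whether AGe had a different effect in M317 than in M318 was tested as an interaction. Over the AGe domain the rMf difference from Wt was 27.5 percentage points in both backgrounds, and the sMf difference 33.2 in M317 and 19.0 in M318, or 28.1 without M318 sMf replicate A. limma called 0 cytosines for rMf, with 61 at an unadjusted p under 0.05, and 6 for sMf, with 87 at an unadjusted p under 0.05. None of the 6 lay in the AGe domain or the AGp domain. The sMf count was 0 with the 4 groups alone (18 at an unadjusted p under 0.05) and with the stricter filter (35). The rMf count was 9, 1 and 3 without M317 rMf replicate A, B or C, 7, 1 and 1 without M317 Wt replicate A, B or C, 8, 2 and 1 without M318 rMf replicate A, B or C, and 4, 1 and 2 without M318 Wt replicate A, B or C. The sMf count was 12 and 32 without M317 sMf replicate A or B, 12 without M317 Wt replicate A, and 10 and 18 without M318 sMf replicate A or B.

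The remaining groups had 1 library each and were not tested. In set A, Col AGp//AGe was methylated in both domains, at 28.8% (AGp) and 34.7% (AGe) in sMf and at 23.3% and 34.4% in rMf. UF2//AGe had 13.0% and 41.5%, and UF4//AGe 13.6% and 34.1%. For both of these the labels give sMf in one field and rMf in another, so the phenotype is not stated. Col ARE//AGe Wt had 1.02% in the AGp domain and 1.38% in the AGe domain, while the Col Wt libraries of set A spanned 1.29% to 1.55% and 0.660% to 1.5%.

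In set B, Met1-1 and ddm1-1 plants were profiled, MET1 being the maintenance methyltransferase of CpG and DDM1 a chromatin remodeler needed for methylation of heterochromatin. As a check of the labels, CpG methylation of the CpG-only domain was 0.833% to 5.49% in the Met1-1 libraries, against 56.2% and 58.7% in Col Wt. With ARE//AGe, both domains were methylated in Met1-1 (AGp 21.5% and AGe 28.5% in sMf, 28.2% and 33.2% in rMf) and in ddm1-1 (27.0% and 33.3% in sMf, 20.9% and 27.9% in rMf). With Ctr//AGe, methylation lay mainly in the AGe domain, at 32.9% in Met1-1, 28.8% in ddm1-1 and 30.6% in Col with rMf flowers, and the AGp domain was at 5.12%, 4.89% and 3.24%. Col Ctr//AGe Wt had 18.7% in the AGe domain and Col AGe rMf of this set 16.1%, against 1.05% and 1.81% in Col Wt. Without a construct, Met1-1 Wt had 1.36% (AGp) and 1.38% (AGe), and ddm1-1 Wt 5.61% and 5.83%.

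In set C, suvh1-2, hdp1-1 and hdp2-1 plants were profiled. SUVH1 binds methylated DNA and promotes transcription, and HDP1 and HDP2 belong to a complex that acts in active DNA demethylation. With ARE//AGe, the AGp and AGe domains were at 19.3% and 29.4% in suvh1-2 sMf, 24.2% and 37.6% in hdp1-1 rMf, 21.9% and 33.3% in hdp1-1 sMf, 20.9% and 32.4% in hdp2-1 rMf, and 24.0% and 36.8% in hdp2-1 sMf. Col ARE//AGe Wt of this set had 1.64% and 3.15%, and Col Wt 1.70% and 0.855%. No ARE//AGe library combines an allele with Wt flowers, or Col with sMf or rMf flowers. The Col libraries of set C also lie in another column block than those with an allele. A difference between the ARE//AGe libraries of Col and of plants with an allele can therefore not be assigned to allele, phenotype or column block. Without a construct the levels were 11.4% and 11.9% in suvh1-2 Wt, 4.30% and 5.08% in hdp1-1 Wt, and 2.22% and 0.861% in hdp2-1 Wt.

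**Figure D3:**
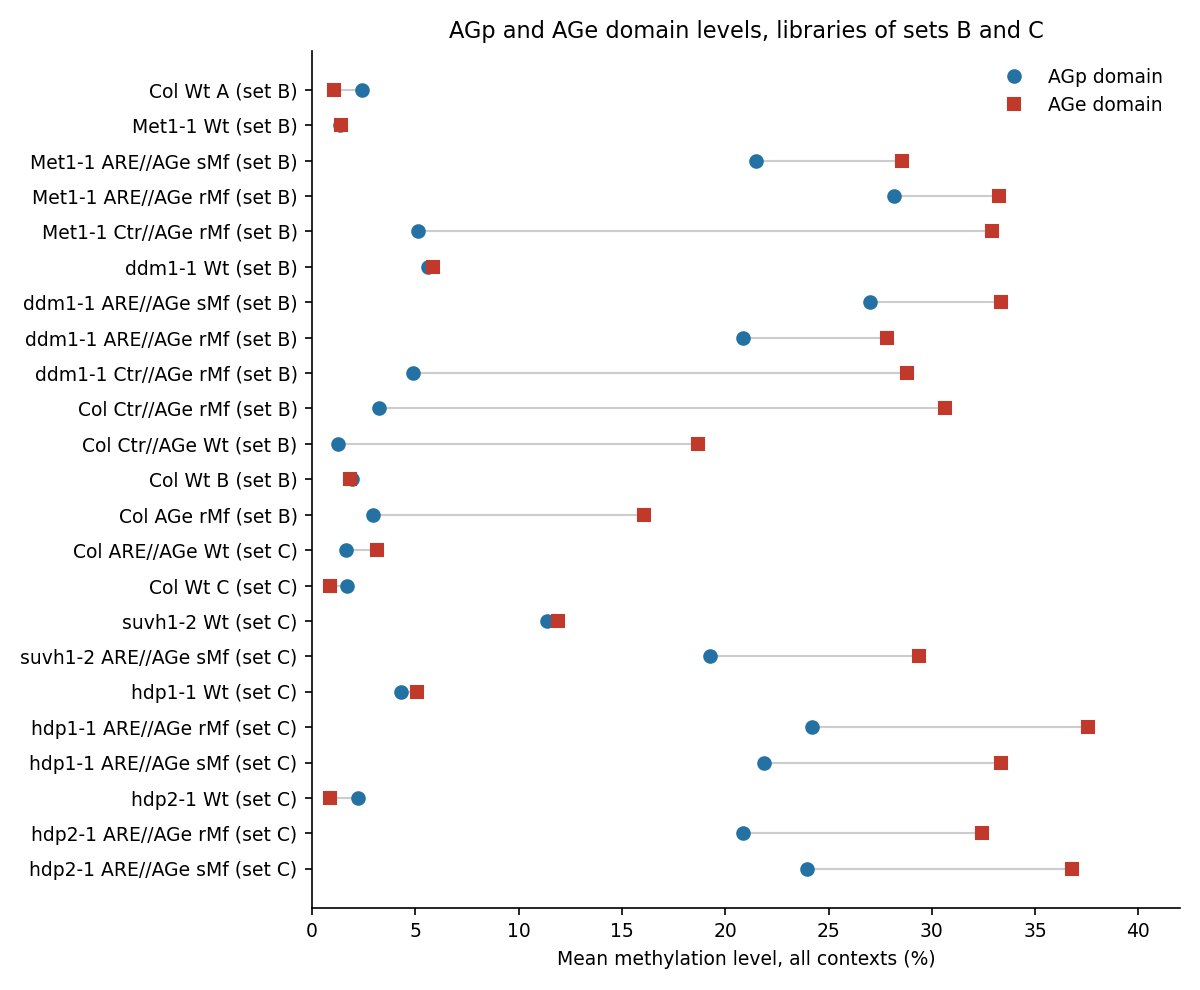
Mean methylation level (%, all contexts) over the AGp domain (circles) and the AGe domain (squares) in each library of sets B and C, 1 library per row. Both domains lie above 19% in every ARE//AGe library of the Met1-1, ddm1-1, suvh1-2, hdp1-1 and hdp2-1 plants, and at or below 3.15% in Col ARE//AGe Wt of set C. The former libraries are pools with sMf or rMf flowers and the latter a pool with Wt flowers, in another column block. Allele, flower phenotype and column block can therefore not be told apart.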

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

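All tests in this part were chosen after the result they bear on had been seen, except the interaction itself. The interaction test called 6 cytosines at which the sMf effect of AGe differed between M317 and M318, and none in the AGe or AGp domain. The signed difference of sMf from Wt was higher in M317 at 5 of them and higher in M318 at 1. The calls depended on the fit, with 0 with the 4 groups alone (18 at an unadjusted p under 0.05 by limma), 0 with the stricter filter (35) and 5 to 32 when 1 library was left out. The M317 sMf group had 2 libraries, so other splits were counted only for the rMf interaction. Its real count was 0, which 100 of 100 drawn splits reach by definition (highest other 10), so the splits decide nothing there.

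Several libraries of plants with an allele label but no construct, outside every tested comparison, had levels above the highest Col Wt library of their set. In set B (highest Col Wt 2.39% in the AGp domain and 1.81% in the AGe domain), ddm1-1 Wt had 5.61% and 5.83%. In set C (1 Col Wt library, at 1.70% and 0.855%), suvh1-2 Wt had 11.4% and 11.9%, hdp1-1 Wt 4.30% and 5.08%, and hdp2-1 Wt 2.22% and 0.861%. The last AGe value exceeds Col Wt by less than the spread between the Col Wt libraries of set B. The Col Wt library of set C lies in another column block than the libraries with an allele, hdp2-1 Wt among them. A rise over it, also in the ratios below, was therefore not separated from a difference between column blocks.

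A candidate explanation for the raised levels in ddm1-1 Wt, suvh1-2 Wt and hdp1-1 Wt is carry-over of DNA or reads from an ARE//AGe library of the same column block, which predicts that the rise over Col Wt has the AGp to AGe ratio of such a library. Over cytosines with a value in the library, the ratio was 0.508 in ddm1-1 Wt (95% bootstrap interval over windows -0.330 to 1.62, ARE//AGe libraries 0.640 to 0.742), 0.878 in suvh1-2 Wt (0.445 to 1.45, ARE//AGe libraries 0.604 to 0.630) and 0.627 in hdp1-1 Wt (0.183 to 1.30, the same ARE//AGe libraries). From the domain means it was 0.782 in ddm1-1 Wt (ARE//AGe libraries 0.708 to 0.818), 0.876 in suvh1-2 Wt and 0.616 in hdp1-1 Wt (0.607 to 0.621 for both), so in ddm1-1 Wt the choice of cytosines moves it from below the range of the ARE//AGe libraries to inside it. Windows at 10% or more in the AGp domain ran from 10380602 to 10381801 in suvh1-2 Wt, as in suvh1-2 ARE//AGe sMf. In ddm1-1 Wt they ran from 10381202 to 10382001, with the end but not the start of the ddm1-1 ARE//AGe libraries, whereas hdp1-1 Wt ended at 10381201 against 10381801. In the AGe domain they ran from 10384602 to 10387001 in suvh1-2 Wt against 10384302 to 10387101. In ddm1-1 Wt they ran there from 10384502 to 10387001 against 10384202 to 10387201 in ddm1-1 ARE//AGe sMf. No run was found there in hdp1-1 Wt, although single windows may have reached 10%. Shorter runs follow from lower levels and shared ends from methylation of the same sequence by either route, so the runs decide nothing; an effect of the allele itself, which the design names, was not tested with 1 library per group, and with these intervals the explanations cannot be told apart.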

How the results depend on the processing

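Of the alternatives planned before the data were examined, a minimum of 10 reads, a count model and Fisher's exact test were not run, because the table holds no read counts. The stricter filter, which stands in for that minimum, the rows as deposited, the column block as a covariate, domain levels, the settings of the interaction and the fits without the segment at 0 were chosen after seeing the data. With no filter, M318 sMf against Wt gave 49 calls, and no other count moved by over 1.5 times. The stricter filter gave 549 for M318 sMf against Wt, 10 for M317 Wt against Col Wt, 14 for AGp Sterile (by construction, since it drops cytosines above 0 in those libraries alone) and 0 for M317 sMf against rMf, M318 sMf against rMf and the sMf interaction. An offset of 0.05 gave 204 for M318 sMf against Wt. The compared groups alone gave 6 for M318 sMf against Wt, 9 for M317 Wt against Col Wt, and 0 for M317 sMf against rMf, M318 sMf against rMf and the sMf interaction. Rows as deposited gave 172 for M318 sMf against Wt, 9 for M317 Wt and 9 for M318 Wt against Col Wt, and 0 for M318 sMf against rMf. Without the segment at 0, which held 13 calls of each, the Wt counts were 1 for M317 and 0 for M318; the p-values of the other 2052 cytosines stayed the same and were adjusted anew, so a pair of calls outside the segment was lost in each through the adjustment. With the column block as a covariate all 12 counts stayed within 1.5 times. Leaving out 1 library (in groups of 2 the lone library is assumed to vary like the other groups) gave 44 to 701 for M318 sMf against Wt, 141 to 563 for AGp Sterile, 15 to 48 and 15 to 51 for M317 Wt and M318 Wt against Col Wt, 8 to 50 and 2 to 16 for sMf against rMf in M317 and M318, 1 to 9 for the rMf and 5 to 32 for the sMf interaction. It gave 513 to 661 and 467 to 587 for M317 sMf and rMf, 529 to 642 for M318 rMf and 456 to 580 for Col AGe rMf against Wt. Among level differences, the median in place of the mean gave 0 in 34 of 42, because most cytosines were listed at 0. The whole-table CpG difference of M317 Wt from Col Wt, 0.037 percentage points, was -0.575 with rows as deposited. Leaving out a library turned the sign of whole-table CpG differences of sMf against rMf (-0.535 to 2.44 in M317, -0.792 to 0.858 in M318), of M317 Wt (-1.20 to 1.28) and M318 Wt (-2.37 to 0.112) against Col Wt and of AGp Sterile (-0.677 to 1.80), of whole-table CHG in M318 sMf against rMf (-2.19 to 0.456) and M317 Wt (-0.191 to 0.0873), of whole-table CHH in M317 Wt (-0.0925 to 0.0812), and of the AGe domain in M318 sMf against rMf (-14.4 to 0.533), M317 Wt (-0.375 to 1.28) and M318 Wt (-0.783 to 0.0582) against Col Wt. Except where construction is named, the cause was not tested. Unknown depth limits every level.

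The replicate letters were not shown to pair the libraries. Correlations of deviations between libraries sharing a letter ran from -0.151 to 0.177, and in no comparison with 3 shared letters did each library correlate best with its own letter. With the replicate block the counts were 666 and 603 for M317 sMf and rMf, 423 and 653 for M318 sMf and rMf and 641 for Col AGe rMf against Wt, 5 and 1 for sMf against rMf, 15 and 15 for the Wt comparisons, 0 for the rMf and 0 for the sMf interaction. In the paired means M317 Wt minus Col Wt turned to -0.384 in CpG and 0.0464 in CHG over the whole table. AGp Sterile carries no letters, so no block could be fitted for it.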

Other observations

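All tests in this part were chosen after the results had been seen. On the AGp side, the run of windows at 10% or more extended from 10380502 to 10381301 in UF2//AGe, from 10381002 to 10381701 in UF4//AGe and from 10381002 to 10383201 in Col AGp//AGe rMf (Col AGp//AGe sMf defined the domain, so its run equals it). In ARE//AGe libraries of plants with an allele the run measured 900 bp in hdp2-1 rMf to 3300 bp in Met1-1 sMf. Col ARE//AGe Wt of sets A and C had no run. The length thus varied among libraries with the same construct label, which also differ in allele, phenotype or column block. Such runs can hold lower windows, and 9 windows reached 10% in hdp2-1 rMf and 19 in Met1-1 sMf. Among the ARE//AGe libraries of set C, the run ended at 10381801 in hdp1-1, hdp2-1 and suvh1-2 plants. In set B it ended at 10382001 in both ddm1-1 ARE//AGe libraries, at 10382601 in Met1-1 rMf and at 10383001 in Met1-1 sMf. The 500-bp bin starting at 10379702, upstream of the AGp domain, was at 22.5% in Met1-1 ARE//AGe sMf and 16.0% in hdp1-1 ARE//AGe sMf, against 1.01% and 1.32% in the rMf libraries of the same alleles. It was at 5.36% in suvh1-2, 3.21% in ddm1-1 and 1.1% in hdp2-1 ARE//AGe sMf, and at 0.171% to 0.873% in the Col Wt libraries of sets B and C. Each value comes from 1 library.

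In the AGe domain, CpG was higher in the sMf than in the rMf ARE//AGe library of each allele with both, at 53.8% and 21.8% in ddm1-1, 47.0% and 23.4% in hdp1-1, 29.3% and 23.5% in hdp2-1, and 27.7% and 24.3% in Met1-1. CHG was at 61.7% and 46.5%, 58.6% and 58.2%, 59.4% and 52.1%, and 60.2% and 64.5% in the same order, and CHH at 28.7% and 26.4%, 29.6% and 36.6%, 35.1% and 31.1%, and 25.3% and 30.7%. These are values of 1 library per group, and the phenotypes were not tested across alleles.

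M318 AGe sMf replicate A had little listed methylation over the AGe domain. Its CpG level in the CpG-only domain was 55.0%, inside the 47.2% to 59.7% of the other libraries of column block 1. This argues against many uncovered cytosines listed as 0 in that domain. It does not measure depth and does not cover the AGe domain, so low depth over the AGe domain is not excluded. A swap with a Wt library of set A is argued against by the highest AGe level among those without a construct, 3.99%. Its own level of 1.54%, near the 0.401% to 1.17% of M318 Wt, leaves a single wrong label and a pool of plants without methylated AGe open. In the segment listed at 0 in M317 and M318 plants it had 11 of 551 cytosines above 0. M318 Wt and M318 rMf replicate A had 0 there, M317 rMf replicate A 10 and Col Wt replicate A 22. These counts bear on the genotype of the pool but do not settle it, so the explanations were not separated. Among 10 splits of the M318 sMf and Wt libraries, 2, the real one included, gave at least the real 329 calls, the highest other (345) being the split that exchanges sMf replicate A with Wt replicate A, which points to that library; 10 splits are too few for a share under 0.05.

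The other comparisons of 3 libraries against 3 also make 10 splits each, too few for a share under 0.05. For M317 rMf against Wt the real split gave 570 calls and the highest other 2, so that 1 split, the real one, reached that count. For M318 rMf against Wt the real split gave 618 and the highest other 3, again with the real split as the 1 that reached it. For M318 sMf against rMf the real split gave 1 and the highest other 146, with 6 splits as large, the real one included. That highest split sets sMf replicate A with rMf replicates A and C, and the cause of its count was not tested.

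The segment listed at 0 in the M317 and M318 libraries of column block 2 was tested in libraries not used to define it. With the run defined on M317 and counted in M318, and the reverse, 2 CHH entries lay above 0, against 171 to 245 expected from the Col libraries of that block, which argues against a covered and unmethylated segment. The count was 1.17% of the lowest expected number, consistent with a lack of reads from this segment in those libraries. In column block 1, M318 Wt and M318 rMf replicate A had 0 of the 551 cytosines above 0, but M317 sMf, M317 Wt, M317 rMf and M318 sMf replicate A had 2, 3, 10 and 11, so the lack may not be complete in those pools. A deletion shared by M317 and M318, another sequence variant and a loss at mapping would all give such zeros, and no value here separates them.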
